A study of Mus musculus with 8 samples.

How the data were processed

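Whole liver RNA was measured in 8 samples from C57BL/6 mice, a common inbred laboratory strain. The animals ate a diet that produces nonalcoholic steatohepatitis (NASH) for 7 weeks, received an adeno-associated virus (AAV) and stayed on the diet for 9 weeks more, 16 weeks in all. The virus carried either Lpcat3 or, as the control, enhanced green fluorescent protein (eGFP), each under the hepatocyte promoter TBG. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed with a FastSelect reagent, stranded libraries were made with a Kapa kit, and single reads of 101 cycles were taken on a NovaSeq instrument.

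The authors deposited 1 table of raw counts, whole numbers of reads per gene that were not normalized, with 40838 rows named by NCBI gene numbers and 1 column per library. The submitters' processing notes name bcl2fastq 2.20, DESeq2 without a version, and the mouse genome build GRCm39. The aligner, the counting program and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, are therefore reported as uncertain. Rn7s1 and Rn7s2 illustrate this, with 2074664 and 2074692 counts over all libraries. Among 16827 rows with at least 100 counts, 34 rows in 17 groups had identical counts in every library.

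Columns were joined to samples by the bracketed codes in the titles, and 0 columns were left without a sample. Gene symbols came from an NCBI RefSeq gene table of the assembly GRCm38, which matched 39397 rows holding 99.5% of the counts. That assembly is not the authors' build, so it served for names and for which genes neighbour each other, and no coordinates are given. No row matched a mitochondrially encoded mRNA, and that list was not analysed here. The list of pancreatic acinar markers had 1 member left after filtering and was not tested.

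Library totals ran from 22433625 to 25651874 counts. Genes with too few counts were removed with filterByExpr (minimum count 10), which left 17438 genes, and 11854 rows were at 0 in every library. The biological coefficient of variation was 16.9%. The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; glmQLFit with robust estimation, glmQLFTest), with TMM scaling and group as the only term. P-values were two-sided, adjusted by Benjamini-Hochberg, and called at 0.05. Standard errors of log2 fold changes come from the same fit. Levels are CPM (counts scaled to a common library size) computed here from the deposited counts with TMM-scaled totals, given as mean ± SD over 4 libraries. Log2 CPM used a prior count of 2. Single measures were compared with a two-sided exact permutation test over the 70 relabellings, whose smallest possible p is 0.0286.

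Gene lists were tested with camera (limma 3.58.1), a test of whether a list shifts relative to the other genes, with a preset correlation of 0.01 and adjustment over the 36 lists tested of the 38 fixed. Camera with an estimated correlation, fry (a test of a list's own shift) and an exact permutation test of a list score stand beside it. The score is the mean log2 CPM of the members relative to the eGFP mean. Lists, main tests and most alternatives were fixed before the data were examined. So was the rule for naming genes. It took Lpcat3, then up to 12 genes per direction that passed with at least 1 CPM, no overlap of the groups and no predicted or clone symbol, filled up to 6 per direction with the smallest p-values where fewer passed, and up to 4 members of each list by p. The genes filled in met the same conditions on CPM, overlap and symbol. Of list members, 4 were taken from the lists on phospholipids, fibrosis, cytokines and mitochondria, and 2 from the others. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

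The same steps were tested on simulated data, with counts for the 17438 genes drawn from the means and library sizes of this comparison and 200 genes changed per simulation. Over 5 simulations edgeR called 28.4% of genes changed 1.5-fold, 71.4% of those changed 2-fold and 92.8% of those changed 4-fold, and 6.1% of its calls were false. These simulations gave 689 calls in all, against 1 in the real data. The Benjamini-Hochberg threshold is looser where more genes change, so these shares are not the power of the real comparison. A list shifted 1.5-fold was called in 5 of 5 simulations, as were 2 of 175 other lists. The simulated genes were drawn independently of each other, so members of a list did not move together. These list counts are therefore no false-call rate for the lists of the real data. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom with quality weights, a fit without robust estimation, each library left out in turn, the replicate number as a block, and the code number as a covariate. The libraries differed from each other by more than sampling noise in every pair (chi-square per gene 9.31 to 139), so no pair looked like repeat deposits of 1 library. This cannot show that they came from separate animals. Figures were drawn with matplotlib 3.10.9.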

Results

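Gene expression was measured by RNA sequencing in 8 mouse livers after 16 weeks of NASH diet, a model of fatty liver with inflammation and fibrosis. Of these, 4 came from the group given AAV-Lpcat3 and 4 from the group given AAV-eGFP, injected after 7 weeks of diet. Lpcat3 encodes lysophosphatidylcholine acyltransferase 3, which inserts polyunsaturated fatty acids into membrane phospholipids. The comparison asks what raised hepatic Lpcat3 does to liver gene expression in established steatohepatitis, and the series title points to mitochondria and disease progression. Depth was even, at 22433625 to 25651874 counts per library. The labels give each sample its own code but do not state that the samples were separate animals, so p-values measure only the spread between these samples.

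The codes carry the numbers 1290, 1317, 1344 and 1345, whose meaning the labels do not give. They divide the libraries unevenly by group, since 3 of 4 eGFP libraries but 1 of 4 Lpcat3 libraries have 1290 or 1317, and the other libraries have 1344 or 1345. This division was made after seeing the data, and its values stand beside the gene list results. A fit with each code number as a covariate takes the group difference only from codes that hold both groups. These are 1290, with Lpcat3 replicate 1 and eGFP replicates 1 and 2, and 1345, with replicate 4 of each group. Such a fit is therefore no adjustment of all 8 libraries. The first principal component held 40.9% of the variance, with eGFP replicate 3 at -46.1 and Lpcat3 replicate 3 at 51.0. The group means on it did not differ by the exact permutation test (p = 0.2), nor did those on the next component with 15.2% (exact p = 0.114).

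**Figure D1:**
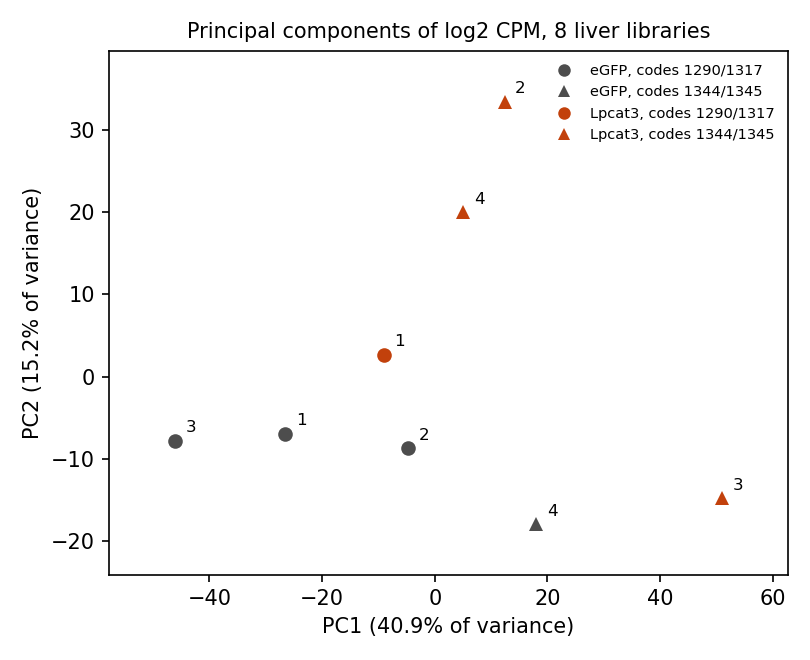
Principal components of log2 CPM in the 8 liver libraries, with each axis giving its share of the variance (40.9% and 15.2%), color giving the group, shape the code number and digits the replicate. The libraries with codes 1290 and 1317 lie at or below -4.75 on the first component, and those with 1344 and 1345 at or above 5.07.

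Lpcat3 (NCBI gene 14792) was 2.37-fold higher in the Lpcat3 group, at 363 ± 86.7 CPM against 153 ± 17.2 CPM (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). Every Lpcat3 library, at 274 to 465 CPM, lay above every eGFP library, at 133 to 173 CPM, as the labels require. The log2 fold change was 1.25 (SE 0.17), with an unadjusted p of 2.82e-05 in edgeR and an adjusted p of 0.164, so Lpcat3 did not pass the test across all genes. DESeq2 called it at an adjusted p of 1.22e-08, and edgeR without Lpcat3 replicate 1 called it at 0.0477. Within the libraries coded 1290 and 1317 the log2 difference was 0.91, and within those coded 1344 and 1345 it was 1.16. Counts per gene cannot separate vector transcripts from the mouse gene's own.

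Across all genes, edgeR called 1 gene higher and 0 lower in the Lpcat3 group. Egfros (NCBI gene 319954), a noncoding RNA gene at the Egfr locus, rose 6.91-fold, from 19.3 ± 5.79 to 134 ± 39.7 CPM (SD, n = 4 each), a log2 fold change of 2.79 (SE 0.27; edgeR adjusted p = 0.0439). Whether its reads belong to Egfros or to overlapping Egfr transcripts depends on strand handling that is not given here. Egfr itself, named after its values were seen, was at 643 ± 343 CPM against 427 ± 121 CPM (edgeR adjusted p = 0.653). At an unadjusted p under 0.05 edgeR counted 575 genes higher and 903 lower, 1478 in all where 872 would be expected by chance. The groups did not overlap for 726 genes, 4.16% of those tested, where chance gives 2.86%. DESeq2 called 27 genes higher and 18 lower. The Egfros call held without Lpcat3 replicate 1 or without Lpcat3 replicate 2, and was lost on leaving out any of the other 6 libraries in turn (edgeR adjusted p = 0.0522 to 0.383) and with the code division as a term (0.237), where the log2 fold change was 2.94 with a larger SE (0.32). Its log2 difference was 2.63 within codes 1290 and 1317 and 3.24 within 1344 and 1345.

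The other genes that the naming rule takes from across all genes did not pass in edgeR. The rule took only genes whose groups did not overlap, so their separation by group is a condition of naming and not a result. It also leaves out genes with predicted or clone symbols and genes under 1 CPM, some of which had smaller p-values. Onecut1, a hepatocyte transcription factor also called HNF6, was at 59.5 ± 17.5 CPM in the Lpcat3 group and 15.3 ± 3.11 CPM in the eGFP group (log2 fold change 1.96, SE 0.22; adjusted p = 0.0752). Zpr1, a zinc finger gene, was at 63.9 ± 13.8 against 32.7 ± 2.53 CPM, Arid5b, a chromatin regulator, at 177 ± 28.5 against 107 ± 9.88 CPM, and Plk3, a stress-responsive kinase, at 79.5 ± 13.0 against 36.1 ± 10.04 CPM. Zfp972 was at 5.05 ± 1.15 against 2.47 ± 0.41 CPM. In the other direction, the Notch target Hes1 was at 8.22 ± 0.84 against 13.6 ± 2.24 CPM, and Eepd1 at 32.5 ± 3.49 against 50.6 ± 7.59 CPM. Nfkbiz was at 16.7 ± 1.26 against 22.1 ± 1.51 CPM, Tnfaip2 at 18.5 ± 1.61 against 30.1 ± 6.33 CPM, Igsf6 at 7.11 ± 1.31 against 13.0 ± 2.82 CPM and the lymphocyte factor Pou2f2 at 3.36 ± 0.46 against 8.73 ± 3.54 CPM. Adjusted p-values for these genes other than Onecut1 ran from 0.228 (Zpr1) to 0.564 (Pou2f2) in edgeR. DESeq2 called all of them, with adjusted p from 1.45e-14 (Onecut1) to 0.0411 (Nfkbiz).

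**Figure D2:**
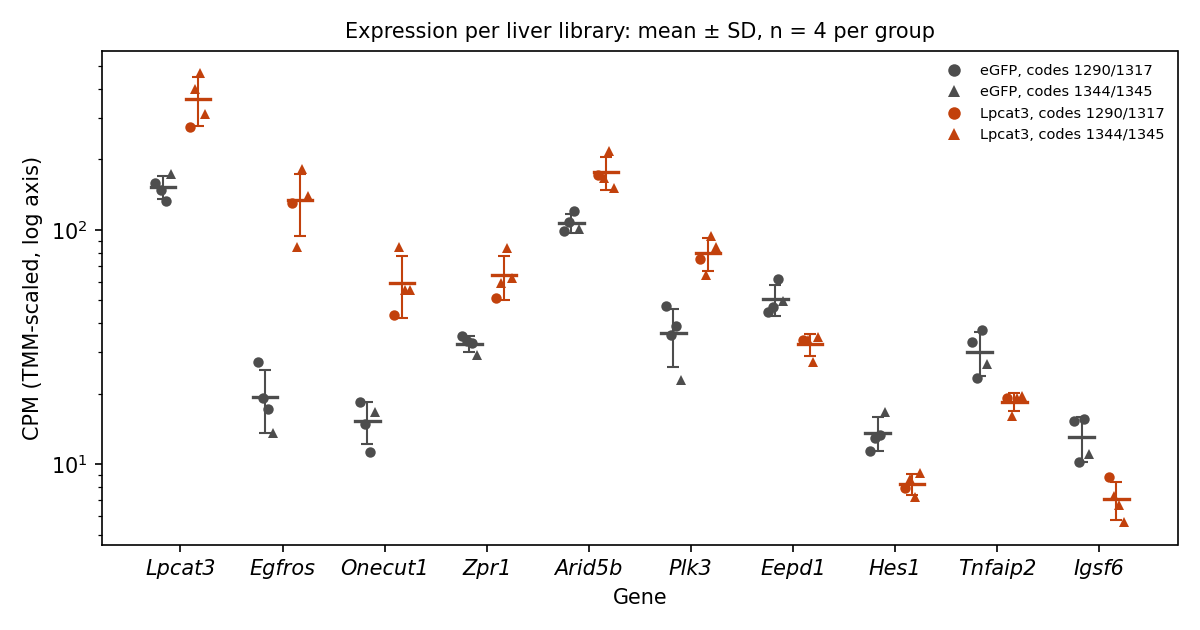
CPM on a log axis for 10 genes in each liver library, with bars for mean and SD of 4 libraries per group and shapes for the code numbers. Lpcat3 libraries lie above every eGFP library for Lpcat3, Egfros, Onecut1, Zpr1, Arid5b and Plk3 and below every eGFP library for Eepd1, Hes1, Tnfaip2 and Igsf6. All but Lpcat3 were named on the condition that the groups did not overlap.

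Genes of phospholipid remodelling and synthesis, a list that includes the delivered Lpcat3 itself, were slightly higher in the Lpcat3 group, 22 of 32 members with a median log2 fold change of 0.07 (camera adjusted p = 0.0136, and adjusted p = 0.468 with an estimated correlation). Without Lpcat3, an alternative chosen after seeing the data, 21 of 31 members were higher with a median of 0.06, and the list was not called (camera adjusted p = 0.0945, and adjusted p = 0.468 with an estimated correlation). Its score difference was then 0.05 in place of 0.09. Adjusted over the list alone 3 members passed, against 0 adjusted over all genes. These were Lpcat3, Lpin1 and Pla2g4a. Lpin1, a phosphatidate phosphatase and coactivator, was at 182 ± 42.3 against 96.8 ± 27.2 CPM, and Pla2g4a, a phospholipase, at 3.31 ± 0.7 against 5.77 ± 1.45 CPM. Chka, a choline kinase, was at 38.2 ± 6.21 against 59.1 ± 26.9 CPM. The adjusted p was 0.0557 without eGFP replicate 3, 0.0522 with the code division as a term and 0.0998 with each code number as a covariate, and the differences in score were 0.10 within codes 1290 and 1317 and 0.07 within 1344 and 1345, or 0.08 and 0.03 without Lpcat3.

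Nuclear genes of oxidative phosphorylation were higher by a small amount in 73 of 76 cases, with a median log2 fold change of 0.08 (camera adjusted p = 1.33e-05, and adjusted p = 0.538 with an estimated correlation). Among them, Ndufs7 of complex I was at 30.0 ± 2.41 against 26.8 ± 1.72 CPM, Uqcrc2 of complex III at 86.7 ± 2.29 against 80.2 ± 2.74 CPM, Atp5d of the ATP synthase at 140 ± 4.68 against 126 ± 11.6 CPM and Ndufa2 at 18.3 ± 0.4 against 16.8 ± 0.81 CPM. No member passed, either over all genes or adjusted over the list alone (0 in each case). The Uqcrc2 difference changed sign with library totals in place of TMM, which lowered the log2 fold change of the median gene by 0.12, and the list's adjusted p was then 0.0528. The adjusted p was 0.0441 with the code division as a term, but 0.931 with each code number as a covariate and 0.548 without both libraries numbered 3. The score difference was 0.10 within codes 1290 and 1317 but -0.03 within 1344 and 1345, so the direction did not hold in both.

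Fatty acid oxidation genes and PPARA targets were higher in 29 of 32 cases (median log2 fold change 0.09; camera adjusted p = 0.00222, and adjusted p = 0.468 with an estimated correlation). Slc25a20, the carnitine carrier of the inner mitochondrial membrane, was at 80.03 ± 1.66 against 68.8 ± 4.23 CPM, Acot1, an acyl-CoA thioesterase, at 36.5 ± 10.7 against 22.4 ± 8.37 CPM, Cyp4a10, an omega-hydroxylase, at 504 ± 138 against 351 ± 100 CPM, and Acaa2, a thiolase, at 405 ± 37.6 against 345 ± 46.8 CPM. None passed adjusted over the list alone or over all genes (0 in each case). Genes of mitochondrial dynamics, biogenesis and mitophagy were higher in 23 of 26 cases (median 0.10; camera adjusted p = 0.00179, and adjusted p = 0.468 with an estimated correlation), among them Mfn1, a fusion protein, at 48.0 ± 2.42 against 42.7 ± 2.25 CPM and Phb2 at 95.5 ± 9.34 against 83.9 ± 6.95 CPM. Without eGFP replicate 3 the adjusted p was 0.0557 for fatty acid oxidation and 0.0522 for mitochondrial dynamics, with the code division as a term it was 0.0349 and 0.22, and with each code number as a covariate 0.152 and, with the direction turned, 0.892. The score differences for fatty acid oxidation were 0.12 and 0.02 within the code divisions, the latter -0.0033 without Lpcat3 replicate 4, and for mitochondrial dynamics 0.07 and 0.00.

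Genes of cholesterol synthesis and uptake were higher in 18 of 23 cases (median log2 fold change 0.08; camera adjusted p = 0.00992, and adjusted p = 0.468 with an estimated correlation). Hsd17b7, an enzyme of the pathway, was at 42.2 ± 1.46 against 34.3 ± 5.06 CPM, without overlap of the groups. The call was lost without Lpcat3 replicate 1 (adjusted p = 0.165) or eGFP replicate 3 (0.153), and held with the code division as a term (0.00873) and with each code number as a covariate (0.0132). The score difference was 0.29 within codes 1290 and 1317 and -0.06 within 1344 and 1345.

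Fibrosis and extracellular matrix genes were lower in 25 of 32 cases, with a median log2 fold change of -0.23 (camera adjusted p = 0.00179, and adjusted p = 0.538 with an estimated correlation). Postn, a matrix protein, was at 14.5 ± 3.31 against 21.4 ± 1.83 CPM, Tgfb1, the fibrogenic cytokine, at 15.1 ± 1.42 against 21.4 ± 5.21 CPM, Loxl2 at 19.2 ± 3.82 against 23.9 ± 3.11 CPM and Vim at 36.0 ± 6.73 against 48.2 ± 15.7 CPM. The collagen gene Col1a1, named after its values were seen, was at 58.0 ± 30.8 against 69.1 ± 9.29 CPM (edgeR adjusted p = 0.862). The list's direction turned without Lpcat3 replicate 3 (adjusted p = 0.799), and with the code division as a term the adjusted p was 0.975. With each code number as a covariate the direction turned and passed (adjusted p = 0.0139), in a fit whose group difference rests on codes 1290 and 1345 only. Score differences were 0.00 within codes 1290 and 1317 and -0.05 within 1344 and 1345. No member passed over all genes or adjusted over the list alone (0 in each case).

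Cytokines and chemokines were lower in 25 of 28 cases (median log2 fold change -0.61; camera adjusted p = 1.49e-08, and adjusted p = 0.468 with an estimated correlation). The neutrophil attractant Cxcl1 was at 5.1 ± 1.79 against 10.6 ± 3.27 CPM, Ccl6 at 15.0 ± 5.14 against 28.8 ± 10.7 CPM and the endotoxin receptor Tlr4 at 12.8 ± 1.43 against 17.2 ± 2.8 CPM, with 0 members past the threshold over all genes or adjusted over the list alone. The adjusted p was 0.00188 with the code division as a term, but 0.187 with each code number as a covariate. Score differences were -0.37 within codes 1290 and 1317 and -0.22 within 1344 and 1345. The former was -0.10 without eGFP replicate 3, and the latter -0.13 without Lpcat3 replicate 3.

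Markers of recruited and lipid-associated macrophages were lower in 19 of 21 cases (median log2 fold change -0.60; camera adjusted p = 9.17e-08, and adjusted p = 0.468 with an estimated correlation). Adgre1, which encodes F4/80, was at 28.5 ± 5.96 against 55.4 ± 21.8 CPM, and Cd44 at 32.4 ± 6.25 against 58.1 ± 22.5 CPM. Kupffer cell markers, which identify the resident liver macrophages, were lower in 8 of 12 cases (median -0.23; camera adjusted p = 0.0193, and adjusted p = 0.468 with an estimated correlation), with Cd5l at 39.0 ± 8.34 against 71.9 ± 22.3 CPM and Vsig4 at 30.7 ± 7.7 against 43.0 ± 4.23 CPM. Cd5l was the 1 member that passed adjusted over the list alone, and 0 passed over all genes. The adjusted p with the code division as a term was 0.00873 for the recruited macrophages and 0.00366 for Kupffer cells. The recruited macrophage score difference was -0.64, and -0.28 without Lpcat3 replicate 3, and the call was lost with each code number as a covariate (adjusted p = 0.851) and without both libraries numbered 3 (0.258). The Kupffer cell call was lost without Lpcat3 replicate 1 (adjusted p = 0.0597), Lpcat3 replicate 4 (0.119) or eGFP replicate 4 (0.269), and with library totals (0.0525). Score differences within codes 1290 and 1317 and within 1344 and 1345 were -0.37 and -0.16 for recruited macrophages and -0.10 and -0.55 for Kupffer cells. Without Lpcat3 replicate 3 the recruited macrophage difference within 1344 and 1345 turned to 0.30. The Kupffer cell difference there is set against eGFP replicate 4 alone, whose score was 0.30 where the other eGFP libraries had -0.14 to -0.07. Pooled, the Kupffer cell difference was -0.24, and -0.39 without Lpcat3 replicate 3.

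Other immune and stress lists were lower as well. Markers of T and NK cells were lower in 11 of 13 cases (camera adjusted p = 0.00992), of B and plasma cells in 9 of 9 (0.0228), and of neutrophils in 5 of 5 (0.0368), and genes of antigen presentation in 10 of 12 (0.00948). With an estimated correlation these calls were lost (adjusted p = 0.479 for antigen presentation and adjusted p = 0.468 for the others). The T and NK cell gene Prf1 was at 0.801 ± 0.179 against 1.41 ± 0.411 CPM. Acute phase proteins were lower in 17 of 18 cases (camera adjusted p = 0.000536, and adjusted p = 0.468 with an estimated correlation), with haptoglobin (Hp) at 1136 ± 190 against 1412 ± 111 CPM. Cell death and p53 targets were lower in 16 of 20 cases (camera adjusted p = 0.00349, and adjusted p = 0.468 with an estimated correlation), with Gdf15 at 5.37 ± 2.79 against 11.8 ± 2.51 CPM and Bbc3 at 3.45 ± 0.375 against 4.77 ± 0.619 CPM, and genes of endoplasmic reticulum stress in 14 of 20 (camera adjusted p = 0.0262, and adjusted p = 0.468 with an estimated correlation). With the code division as a term acute phase proteins kept a call (adjusted p = 0.0349), and the other lists of this group did not (adjusted p = 0.135 to 0.447). Acute phase proteins were also called without each library in turn, while each of the other lists here lost its call without at least 1 library, among them eGFP replicate 3 for all but B and plasma cells (adjusted p = 0.0631 to 0.48), and Lpcat3 replicate 3 for B and plasma cells (0.126). With each code number as a covariate all calls of this group were lost (adjusted p = 0.237 to 0.915; acute phase proteins 0.569) and neutrophils turned, and with library totals the calls were lost of T and NK cells, B and plasma cells and neutrophils (adjusted p = 0.0786 to 0.152). Score differences within codes 1290 and 1317 and within 1344 and 1345 were -0.39 and -0.01 for T and NK cells, -0.05 and -0.44 for B and plasma cells, -0.37 and -0.07 for neutrophils and -0.03 and -0.27 for acute phase proteins. The smaller of these turned on leaving out 1 library: T and NK cells to 0.10 without Lpcat3 replicate 4, B and plasma cells to 0.04 without eGFP replicate 1, and acute phase proteins to 0.03 without eGFP replicate 3. For neutrophils both turned, to 0.15 without eGFP replicate 3 and to 0.25 without Lpcat3 replicate 3. They were -0.18 and -0.10 for cell death, but -0.19 and 0.01 for antigen presentation and -0.13 and 0.02 for endoplasmic reticulum stress, whose direction did not hold in both.

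Markers of parenchymal and structural cells moved in both directions. Endothelial markers were lower in 14 of 14 cases (median log2 fold change -0.17; camera adjusted p = 0.000142, and adjusted p = 0.468 with an estimated correlation), with Cdh5 at 48.6 ± 5.91 against 64.0 ± 3.95 CPM, the 1 member that passed adjusted over the list alone against 0 over all genes. Cholangiocyte and progenitor markers were higher in 11 of 13 cases (median 0.42; camera adjusted p = 0.00179, and adjusted p = 0.468 with an estimated correlation), with Epcam at 3.94 ± 1.95 against 2.1 ± 0.642 CPM. Hepatocyte markers were higher in 16 of 17 cases (camera adjusted p = 0.00452, and adjusted p = 0.524 with an estimated correlation), with Tat at 1090 ± 445 against 577 ± 234 CPM, and pericentral hepatocyte genes in 12 of 15 (camera adjusted p = 0.00258, and adjusted p = 0.468 with an estimated correlation), with Cyp2e1 at 8145 ± 1717 against 5700 ± 1853 CPM. Sex-biased liver genes were higher in 12 of 14 cases (camera adjusted p = 0.00349, and adjusted p = 0.468 with an estimated correlation), with Hsd3b5 at 14.1 ± 14.5 against 0.839 ± 1.29 CPM. Hsd3b5 was at 2.77 CPM in eGFP replicate 4 and 0.111 to 0.314 CPM in the other eGFP libraries, and its log2 difference was -0.07 within codes 1290 and 1317 and 2.201 within 1344 and 1345. That list mixes male-biased genes, 10 of 10 higher, with female-biased genes, 2 of 4 higher. With the code division as a term the adjusted p was 0.00366 for endothelial and 0.00245 for cholangiocyte markers, 0.29 for hepatocyte markers, 0.357 for pericentral genes and 0.565 for sex-biased genes. Without eGFP replicate 3 the hepatocyte (adjusted p = 0.153) and pericentral (0.0631) calls were lost, the former also without Lpcat3 replicate 3 (0.206). With each code number as a covariate the endothelial (adjusted p = 0.0201) and cholangiocyte (0.00251) calls held, and hepatocyte (0.569), pericentral (0.931) and sex-biased (0.436) genes turned. Score differences within codes 1290 and 1317 and within 1344 and 1345 were -0.03 and -0.23 for endothelial and 0.16 and 0.66 for cholangiocyte markers, with the endothelial difference within 1290 and 1317 at 0.00 without eGFP replicate 1. For hepatocyte markers they were 0.18 and -0.04 and for pericentral genes 0.25 and -0.17, and for sex-biased genes they were -0.08 and -0.03, opposite to the pooled direction in both. The cholangiocyte difference within 1344 and 1345 is set against eGFP replicate 4 alone, the lowest eGFP library (score -0.30, others -0.02 to 0.32). Lpcat3 replicate 3 had a cholangiocyte score of -0.33, below every eGFP library. The exact permutation p of that list's score was 0.286.

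The other 15 lists were not called, with camera adjusted p from 0.0517 to 0.916. They covered mitochondrial chaperones and proteases, fatty acid and triglyceride synthesis, LXR targets, VLDL assembly, lipid droplets, bile acids, NRF2 targets, cell cycle, interferon response, the circadian clock, periportal hepatocytes, dendritic cells, stellate cells, red blood cells, and mesothelial and adipose cells. Ctsc, at 82.3 ± 19.8 against 132 ± 14.5 CPM, was the 1 periportal member that passed adjusted over the list alone. For mesothelial and adipose markers the median log2 fold change (-0.09) and the camera direction differed in sign.

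In all, camera with its preset correlation called 21 of 36 lists, 9 higher and 12 lower. Every other division of the 8 libraries into 4 and 4 also gave called lists, from 1 to 22 of them. With an estimated correlation 0 were called, and fry called 0 (3 at an unadjusted p under 0.05). The exact permutation test of list scores cannot call a few lists after adjustment over 36, because its smallest p is 0.0286, so its adjusted values are no check of these calls. Unadjusted, 1 list was under 0.05, phospholipid remodelling (exact p = 0.0286), which includes the delivered gene and has an exact p of 0.171 without it. Within both code divisions 12 of the 21 lists had the direction of the pooled result. Of these, 5 kept it there on leaving out each library in turn where another of its group remained. They were phospholipid remodelling, cytokines and chemokines, cell death, Kupffer cells and cholangiocytes. Lpcat3 replicate 1 and eGFP replicate 4, each alone in its group there, could not be left out, and each difference rests on 1 of them. For Kupffer cells eGFP replicate 4 stood apart from its group (score 0.30, others -0.14 to -0.07). Without it the pooled Kupffer call was lost (camera adjusted p = 0.269). For cholangiocytes eGFP replicate 4 was the lowest eGFP library (score -0.30), and Lpcat3 replicate 3 (-0.33) lay below every eGFP library. Of the 21 lists, 9 stayed called with the code division as a term, 4 with each code number as a covariate and 6 without both libraries numbered 3. The count of 4 comes from a fit whose group difference rests on codes 1290 and 1345 only. On leaving out each library in turn 7 of the 21 kept their call throughout: cytokines and chemokines, nuclear oxidative phosphorylation, acute phase proteins, sex-biased genes, recruited macrophages, endothelial cells and cholangiocytes. The phospholipid, oxidative phosphorylation, fatty acid oxidation, mitochondrial dynamics and cholesterol lists rose by a median of 0.07 to 0.10. Library totals lowered the median gene by more, 0.12. Their counts of higher members therefore hold with TMM scaling, relative to other genes.

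**Figure D3:**
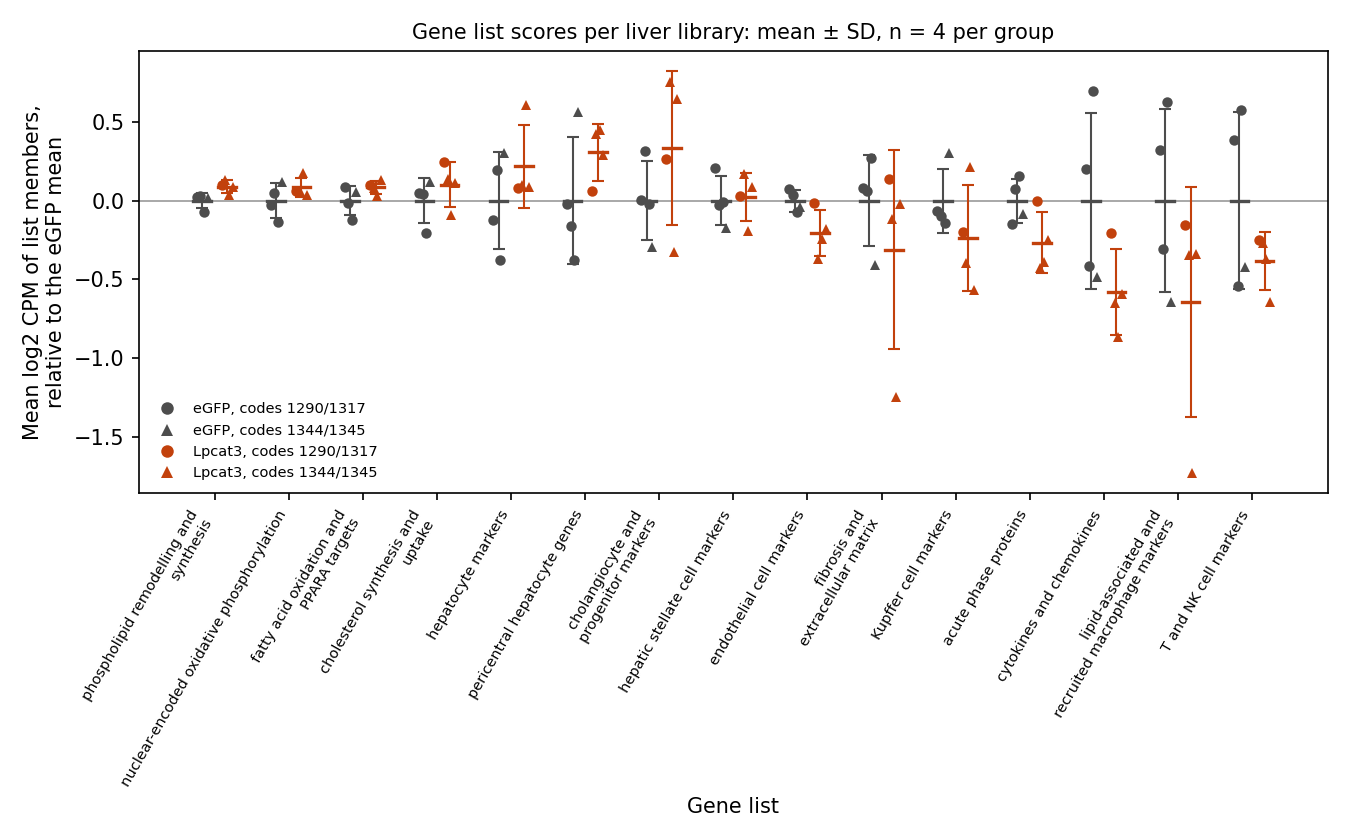
Mean log2 CPM of the members of 15 gene lists in each liver library, relative to the eGFP mean, with bars for mean and SD of 4 libraries per group and shapes for the code numbers. Lpcat3 replicate 3 lies lowest for recruited and lipid-associated macrophage markers (-1.73) and for fibrosis genes (-1.25).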

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

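All values in the next paragraph are ones where a single library lay far from the other 3 of its group by Dixon's criterion, which picks out about 1 in 20 groups by chance, and 13 of 256 did so. Of the tests below, those of an estimated correlation, of cell shares and of the code numbers were chosen after the result was seen.

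Lpcat3 replicate 3 was lowest for recruited macrophage markers (score -1.73, others -0.35 to -0.16), lipid droplet genes (-0.57) and cell cycle genes (-0.44), and highest for hepatocyte markers (0.61, others 0.08 to 0.10). It was also lowest for Eepd1 (27.4 CPM) and S100a8 (0.479 CPM). In Lpcat3 replicate 1, Hp was at 1418 CPM and Cd44 at 41.7 CPM, both highest, and in Lpcat3 replicate 2 Tnfaip2 was lowest at 16.1 CPM. Among eGFP libraries, replicate 3 was lowest for phospholipid remodelling (-0.070) and VLDL assembly (-0.18), replicate 1 highest for cell cycle genes (0.32) and replicate 4 highest for Kupffer cell markers (0.30).

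The pattern weighed first is the set of lists with lower immune and higher hepatocyte and mitochondrial genes in the Lpcat3 group. Without Lpcat3 replicate 3, 16 of the 21 called lists stayed called, which argues against that library as the only source for those lists. The hepatocyte (adjusted p = 0.206), neutrophil (0.173), B and plasma cell (0.126) and endoplasmic reticulum stress (0.11) calls were then lost, and the fibrosis list turned (0.799). Without eGFP replicate 3, 10 of the 21 stayed called, the fewest on leaving out any 1 library. The pattern may reflect genes of a list moving together between libraries of either group, since 0 of the 21 calls held with an estimated correlation. It may also follow the codes 1290 and 1317 against 1344 and 1345, since 9 of the 21 held with that division as a term. A lower share of every other cell type would lower cholangiocyte and stellate markers as much as macrophage markers; they differed by 0.82 on the log2 scale between groups (exact permutation p = 0.0857), so the 4 libraries per group leave this open. A lost call by itself does not show that a list follows the code division. Phospholipid remodelling lost its call (camera adjusted p = 0.0522), but its score differences within the divisions were 0.10 and 0.07, against 0.09 pooled. Without the delivered Lpcat3 they were 0.08 and 0.03, against 0.05. Cell death and p53 targets also lost their call (camera adjusted p = 0.171), with score differences of -0.18 and -0.10, against -0.26 pooled. A kept call does not by itself set a list apart from the division. Oxidative phosphorylation kept its call with score differences of 0.10 and -0.03, and cholesterol synthesis with 0.29 and -0.06. An effect of Lpcat3 also stays open. It cannot be separated from the code division for the other lists that lost their call, nor for oxidative phosphorylation and cholesterol synthesis.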

How the results depend on the processing

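The direction of Lpcat3 held in all alternatives, with log2 fold changes of 0.84 to 1.36 and 1.10 to 1.36 on leaving out each library. It passed with library totals (1.12) and DESeq2 (1.25). Genes higher numbered 1 in edgeR, 3 with library totals, 2 without robust estimation, 2 at an adjusted p under 0.1, 27 with DESeq2 and 0 without the low-count filter, with code number as a covariate, with the code division or without both libraries numbered 3 (the last 2 chosen after seeing the data). Leaving out each library gave 0 to 7, 7 without Lpcat3 replicate 1. Genes lower numbered 0, and 18 with DESeq2. Samples sharing a replicate number correlated at 0.357, -0.11, -0.47 and -0.16, so the numbers do not pair the samples, and with replicate number as a block 0 genes were higher. The cause of these differences was not tested. Genes changed 1.5-fold were called in 28.4% of simulated cases, which limits what this depth and spread can show. That share is likely too high for the real data, where fewer genes were called and the threshold was stricter. Called lists numbered 21, and 19 of them stayed called with the block.

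In the lists, adjusted p-values changed as follows. With an estimated correlation they were 0.468 for phospholipids, cytokines and fatty acid oxidation and 0.538 for fibrosis and oxidative phosphorylation. By fry they were 0.347 (phospholipids), 0.493 (fibrosis), 0.38 (cytokines, fatty acid oxidation), 0.418 (oxidative phosphorylation) and, turned, 0.983 (mesothelial). With code number as a covariate they were 0.0998 (phospholipids), 0.187 (cytokines), 0.931 (oxidative phosphorylation) and 0.152 (fatty acid oxidation); directions turned for fibrosis (0.0139, past the threshold), mitochondrial dynamics (0.892), VLDL (0.851), lipid droplets, bile acids, hepatocytes and neutrophils (0.569 each), clock (0.882), pericentral (0.931), periportal (0.246), sex-biased (0.436) and mesothelial (0.0998). Without both libraries numbered 3 they were 0.068 (phospholipids), 0.548 (oxidative phosphorylation) and 0.0516 (fatty acid oxidation), and LXR targets gained a call (0.0241); directions turned for fibrosis (0.181), VLDL (0.528), lipid droplets (0.32), hepatocytes (0.641), periportal (0.00791), neutrophils (0.666), red blood cells (0.75) and mesothelial (0.258). Without the delivered Lpcat3, also chosen after seeing the data, phospholipids had 0.0945, since that gene held part of the shift. With the code division they were 0.0522 (phospholipids) and 0.975 (fibrosis), and turned for interferon (0.611), periportal (0.968) and mesothelial (0.902). With library totals oxidative phosphorylation had 0.0528, calls were lost for Kupffer (0.0525), T and NK (0.0786), B and plasma cells (0.0942) and neutrophils (0.152), and gained for bile acids (0.0183) and clock (0.00324). Calls lost without a turn numbered 21 with an estimated correlation, 21 by fry, 11 with code number, 12 with the code division and 12 without both libraries numbered 3. With at least 1 CPM in 4 libraries T and NK (0.335) and B and plasma cells (0.113) lost their calls and bile acids gained one (0.0321), as did bile acids and clock with no filter (0.0451, 0.0366) and without robust estimation (0.0492 each). Neutrophil markers had fewer than 3 members left with at least 1 CPM in 4 libraries and could not be tested there. With the block endoplasmic reticulum stress (0.0616) and neutrophils (0.0789) lost theirs and interferon gained one (0.0136). With limma-voom endoplasmic reticulum stress (0.0567), B and plasma cells (0.056) and neutrophils (0.269) lost theirs, mitochondrial chaperones (0.0219), LXR targets (0.0494), interferon (0.0307) and clock (0.0424) gained one, and periportal (0.963), red blood cells (0.916) and mesothelial (0.595) turned. Leaving out each library gave 0.00856 to 0.0557 (phospholipids), 1.16e-05 to 0.799 (fibrosis), 0.000301 to 0.0557 (fatty acid oxidation), 0.0139 to 0.923 (fatty acid synthesis), 0.316 to 0.873 (VLDL), 0.0675 to 0.831 (lipid droplets), 0.0077 to 0.874 (interferon), 0.0196 to 0.922 (periportal), 0.0787 to 0.818 (stellate), 0.13 to 0.981 (red blood cells) and 0.243 to 0.845 (mesothelial). The causes were not tested.

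Named genes turned in log2 fold change as follows. With code number as a covariate Vim was 0.027, Cfd -0.080, Col1a1 0.25 and Egfr -0.23. Without both libraries numbered 3 Col1a1 was 0.13, and it ran from -0.47 to 0.078 on leaving out each library. The gene Egfr was at -2.86e-05 with the code division. The cause of these was not tested. The gene Uqcrc2 was at -0.00833 with library totals, which lowered the median gene by as much (-0.12), so it stayed above the median gene.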

Other observations

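Genes that respond to growth hormone, chosen after their values were seen, differed in mean between the groups. Cish, a STAT5-induced inhibitor, was at 16.3 ± 6.02 CPM in the Lpcat3 group against 5.59 ± 1.91 CPM (SD, n = 4 each), and Socs2, another such inhibitor, at 21.3 ± 6.2 against 10.9 ± 1.76 CPM. Bcl6, a repressor that growth hormone lowers, was at 45.4 ± 12.3 against 72.7 ± 10.9 CPM. None of them passed in edgeR (adjusted p = 0.564 for each), and DESeq2 called Cish (adjusted p = 0.00185) and Socs2 (0.00589). DESeq2 also called, among genes likewise chosen after their values were seen, Alas1, the first enzyme of heme synthesis, at 1046 against 482 CPM (adjusted p = 0.00567), and Noct, a rhythmic gene, at 56.6 against 21.4 CPM (0.00774). The macrophage gene Trem2, also chosen after its values were seen, was at 2.1 ± 1.19 against 3.2 ± 0.952 CPM (edgeR adjusted p = 0.7).

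The codes 1344 and 1345 against 1290 and 1317 differed in 9 genes higher and 4 lower in edgeR with group in the model. Camera called 17 lists for this division, each in the direction that list had between the groups. Among them, fibrosis genes (camera adjusted p = 5.8e-09) and recruited macrophages (2e-07) were lower. Pericentral genes (2.61e-11), sex-biased genes (1.47e-10) and oxidative phosphorylation (0.000114) were higher. The fold changes of the division correlated with those of the group at 0.496 across genes. This division was singled out after seeing that it gave the most genes, so these values are no independent evidence for it. In deviations from the group means across genes, which are not independent replicates, libraries sharing a code number correlated at 0.357, -0.0689 and -0.161 between groups. Within a group, where centring pulls values below 0, they correlated at -0.334 and -0.396. The genes named for this difference were chosen after their values were seen. Slco1a1, a male-biased transporter, was at 232 ± 74.9 against 45.2 ± 6.52 CPM (edgeR adjusted p = 0.0444), and Abhd6, a lipid hydrolase, at 84.4 ± 2.12 against 49.2 ± 3.35 CPM (0.0229). Clpx, a mitochondrial protease subunit, was lower at 74.1 ± 6.63 against 117 ± 3.22 CPM (0.0337), as was Insig2, a sterol sensor, at 137 ± 8.86 against 220.0 ± 9.47 CPM (0.0337). Major urinary protein genes were higher without passing, for example Mup7 at 5569 ± 1990 against 1050 ± 251 CPM (0.0548), a family of near-identical copies whose counts are uncertain. Ddx3y was at 64.9 to 85.6 CPM and Xist at 0.275 to 3.84 CPM over all libraries.

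Other divisions of the 8 libraries into 4 and 4 did not exclude chance for the counts over all genes or of called lists. Camera called lists in each of the 35 divisions, from 1 to 22 of them, so having called lists does not mark the real one. Of the 35 divisions, the real one included in each count, 2 gave at least as many genes past the threshold in edgeR as the real one (1, highest other 260), 6 as many at an unadjusted p under 0.05 (1478, highest other 3500), 4 as many in DESeq2 (45, highest other 1235) and 3 as many called lists (21, highest other 22). The division with 260 and 1235 genes was codes 1290 and 1317 against 1344 and 1345, which points to a structure of the samples beyond the groups. As the highest of the 35, picked for its counts, it does not tie that structure to the codes. With that division as a term edgeR called 0 genes for the group, although the folds of the leading genes stayed about as large. Egfros went from a log2 fold change of 2.79 (SE 0.27) to 2.94 (SE 0.32), Onecut1 from 1.96 (SE 0.22) to 1.75 (SE 0.23) and Lpcat3 from 1.25 (SE 0.17) to 1.04 (SE 0.15), so the lost Egfros call reflects a wider error and fewer degrees of freedom, not a smaller fold.

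For the paragraphs below, the tests of clock phase, growth hormone targets, neighbouring genes and the Egfr ratio were chosen after the result was seen. The differences in Cish, Socs2, Onecut1 and Bcl6 may follow growth hormone signalling. In a list of 11 other genes tied to growth hormone, which includes Ghr, Stat5a and Hnf4a, 10 were higher. The mean difference was 0.52 on the log2 scale (exact permutation p = 0.0857), and 0.24 within codes 1290 and 1317 and 0.19 within 1344 and 1345. The largest log2 fold changes were those of Mup1 (1.75) and Mup7 (1.47), of the family whose counts are uncertain. The others ran from -0.27 (Stat5a) to 0.60 (Serpina3k). Cish, Socs2, Onecut1 and Bcl6 might instead follow time of collection. Clock genes of opposite phase differed by 0.53 (exact permutation p = 0.114), by 0.32 within codes 1290 and 1317 and by -0.01 within 1344 and 1345. Each of these divisions has 1 library in one group, and neither explanation could be settled with 4 libraries per group.

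Neighbouring genes stood together among the 50 genes with the smallest p-values. There were 4 adjacent pairs, where 10000 random draws of 50 tested genes had a mean of 0.148 and a maximum of 3. The permutation p was 0.0001, the smallest possible, with or without matching on expression, which argues against chance placement of these genes. The pairs were noticed in this same list. The draws do not show whether another division of the libraries would also give such pairs. The pairs, named after their values were seen, were Gm39584 with Egfros, Zpr1 with Bud13, Gm33562 with Gm16551, and Gm16551 with Onecut1. A fixed share of Egfr reads counted at Egfros and Gm39584, which lie within it, would leave their ratios to Egfr alike, but the Egfros ratio was 2.31 higher on the log2 scale in the Lpcat3 group (exact permutation p = 0.0571). In edgeR with the Egfr counts as offset the difference was 2.41 (SE 0.54) for Egfros and 2.32 (SE 0.64) for Gm39584. With the code division as a term the differences were 3.03 and 2.88. Egfros and Gm39584 were picked for small p-values between the groups in these same libraries, while Egfr did not pass. A higher ratio to Egfr was therefore partly given by the choice of genes, and the exact test missed 0.05. These values do not settle whether a fixed share holds. A changed share of reads from overlapping genes could also give such pairs, and shared regulation of neighbouring genes was not tested.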
